A study of Mus musculus with 2 samples.

How the data were processed

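Pancreatic islet cells of C57BL/6J mice aged 13 weeks were profiled by droplet single-cell RNA sequencing, with 1 library labelled CD (a name the labels do not expand) and 1 library from mice on a high-fat diet (HFD). Per the labels' protocols, islets were released by collagenase P injected through the bile duct, purified on a density gradient, picked by hand, dispersed with TrypLE, and made into 10x Genomics 3' v3 libraries sequenced on a NovaSeq. The number of mice behind either library is not given in the sources used here.

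The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. Per the submitters' processing notes the reads were processed with Cell Ranger 6.0.1 against mm10, whereas per the file headers the matrices were written by software version 3.0.2. The files list every possible barcode, so the authors had not selected cells before deposit. No annotation release is given in the sources used here. Of the listed gene identifiers, 99.9% matched GENCODE release M21 for GRCm38 (the same build as mm10), from which positions and transcript lengths were taken.

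The CD library held 265836346 UMIs and the HFD library 271527648. A barcode was kept as a cell with at least 1500 UMIs, at least 500 detected genes and at most 15% of UMIs on mitochondrially encoded genes. Doublet scores came from the scrublet routine in scanpy 1.11.5, and the highest scores were removed at a rate of 0.8% per 1000 kept barcodes, which took 748 of 9667 CD barcodes and 1164 of 12062 HFD barcodes. Free RNA, which enters droplets from lysed cells, was profiled in barcodes with 10 to 100 UMIs of the same library.

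Cells of both libraries were clustered together in Python 3.11.15 on log-normalized counts (10000 per cell) with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9), without integration. Clusters were named from marker genes fixed before the data were examined. The rule that scored the markers was set after seeing the data. Each marker's level was divided by its highest level over clusters of at least 20 cells, and the class with the highest mean share was taken if at least 3 of its markers were each seen in at least 10% of the cluster's cells. A cluster stayed unnamed if another endocrine class scored over 0.5 times as much, if another class apart from erythroid scored over 0.9 times as much, or if markers of another class outnumbered its own among its top 10 genes. Subclusters were made within the β-like, α-like and δ-like classes at resolution 0.4 on 1000 variable genes and 15 components, after scaling within each library. Their sizes were to be compared only where none of the 10 leading genes differed over 1.5 times between the class sums of the 2 libraries.

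With 1 library per diet there was no replicate check, and no test between diets was made. UMIs were summed per class and library and scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, giving CPM (counts scaled by the total). The ratio of HFD to CD has an exact 95% interval from the conditional binomial distribution, and a share of cells has an exact (Clopper-Pearson) 95% interval. All intervals cover counting error only. A difference of shares has an interval built from both exact intervals. A count of 0 is given with the share that 3 counts allow.

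The rule for named genes was fixed before the data were examined. A gene needed at least 50 UMIs and 50 CPM in the library where it was higher, and a level there at least 3 times what free RNA would bring. The free RNA share of a class was the median, over hormone and acinar genes foreign to it with at least 50 UMIs in the empty barcodes, of the class level over the level in those barcodes. Genes were ranked by the interval bound nearest a ratio of 1, and the 10 highest and 10 lowest were named in β-like and α-like cells and the 6 highest and 6 lowest in δ-like cells. Ribosomal protein genes, mitochondrially encoded genes and unnamed gene models were left out of the ranking. The hormone genes and members of each preset list (those with the most UMIs and those with the bound farthest from 1) were added; the restriction to 2 members per list and class was set after seeing the data. Some of the genes that these rules select are not reported. Hmgn2, Tmsb15b2 and the pair Hspa1a and Hspa1b have close copies or pseudogenes elsewhere in the genome, between which the counting could have divided reads, so their values are uncertain.

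There were 19 preset gene lists: β identity, β immaturity and disallowed genes, α identity, δ identity, secretory granules, the unfolded protein response, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, glycolysis, fatty acid oxidation, cholesterol synthesis, fatty acid synthesis, cell cycle, the immediate early and dissociation response, antioxidant and metal response, antigen presentation and interferon response, amino acid transport, cAMP and incretin signalling, and ribosomal proteins. Members entered with at least 20 UMIs over both sums. A list was summarised by its median log2 ratio of CPM plus 1, and by the percentile of that median among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The counting interval of a median came from 400 Poisson redraws of the sums.

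Cells with cell cycle transcripts were those with at least 2 of Mki67, Top2a, Cdk1, Ccna2, Birc5 and Ube2c detected after every cell was thinned to 3000 UMIs, with shallower cells left out. The steps from sums to intervals were tested on simulated data with 200 changed genes per class. These were drawn from genes at 20 CPM or more, leaving out hormone genes and Ttr, so genes at lower levels were not covered. Both simulated libraries were Poisson draws from the same pooled profile. How often the interval held the true ratio of unchanged genes was therefore set by that design, and variation between animals was not simulated. In the simulated β-like comparison of 14522 genes, the interval lay on the right side of 1 for 100% of genes changed 1.5-fold and 100% of those changed 2-fold, and it held the true ratio for 95.4% of unchanged genes. For the α-like comparison of 12159 genes these values were 100%, 100% and 95.8%. For the δ-like comparison of 10980 genes they were 88% at 1.5-fold, 100% at 2-fold and 96% for unchanged genes.

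Alternatives were fixed before the data were examined. They covered UMI minimums of 3000 and 800 and a minimum per library, mitochondrial limits of 10% and 25%, no doublet removal and removal of 2 times as many, resolutions of 0.5 and 2, clustering without hormone genes, clustering of each library alone, and a class for each cell from the marker lists. For subclusters they covered resolutions of 0.2 and 0.8 and no scaling within library. For expression they also covered total counts, DESeq2 1.42.0 size factors, scaling without hormone and mitochondrial genes, subtraction of free RNA, equal weight for every cell, thinned cells and a minimum of 100 UMIs. Removal of a trend with transcript length (lowess in statsmodels 0.14.6, fraction 0.3, over genes at 20 CPM or more) was added after seeing the data.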

Results

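Single-cell transcriptomes of pancreatic islets were obtained from mice in 2 groups, CD and high-fat diet (HFD), with 1 library each, to find subpopulations of α, β and δ cells in a prediabetes model. After filtering, the CD library held 8919 cells with a median of 21221 UMIs and 2880 genes per cell, and the HFD library 10898 cells with a median of 16978 UMIs and 2472 genes. Cells held 78.5% of all UMIs in CD and 74.9% in HFD. The median mitochondrial share per cell was 2.76% in CD and 4.24% in HFD. Because each diet has 1 library, no difference given here has a replicate check, and each describes these libraries and not the diets.

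The first comparison asked which endocrine cells were present in either diet. Insulin-producing β-like cells were the largest class, with 72.9% of 7328 endocrine cells in CD (95% interval 71.9 to 73.9) and 66.7% of 9426 in HFD (65.7 to 67.6). Glucagon-producing α-like cells made up 16.3% in CD (15.5 to 17.2) and 21.7% in HFD (20.8 to 22.5). Somatostatin-producing δ-like cells made up 6.97% (6.4 to 7.58) and 6.37% (5.88 to 6.88). PP-like cells, which make pancreatic polypeptide, made up 3.81% (3.38 to 4.27) and 5.3% (4.86 to 5.78). The differences between HFD and CD were -6.24 percentage points for β-like cells (-7.64 to -4.84) and 5.35 for α-like cells (4.15 to 6.54). They were -0.608 for δ-like cells (-1.38 to 0.16) and 1.5 for PP-like cells (0.855 to 2.13). When each cell was classed from the marker lists these differences were -0.747, 2.7, -1.03 and -0.925 points, so that the PP-like difference changed sign. The shares in CD and HFD were then 64.3% and 63.5% for β-like, 15.1% and 17.8% for α-like, 9.53% and 8.5% for δ-like and 11.0% and 10.1% for PP-like cells. With a UMI minimum of 3000 or 800, a mitochondrial limit of 10% or clustering without hormone genes, the δ-like difference lay between -2.93 and -2.34 points and the β-like difference between -4.01 and -3.36. The δ-like difference was -1.33 with 2 times as many doublets removed, -0.935 at resolution 0.5 and -0.957 with each library clustered alone. The PP-like difference was 0.656 points with the minimum of 3000 UMIs, 0.991 with the minimum per library, 0.902 with a mitochondrial limit of 25%, 0.903 with 2 times as many doublets removed and 0.641 with each library clustered alone. Median depth was 26734 UMIs in CD and 23499 in HFD for β-like cells, 9412 and 7667 for α-like cells, 6429 and 4854 for δ-like cells and 15278 and 10327 for PP-like cells. A UMI minimum can set part of these shares.

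**Figure D1:**
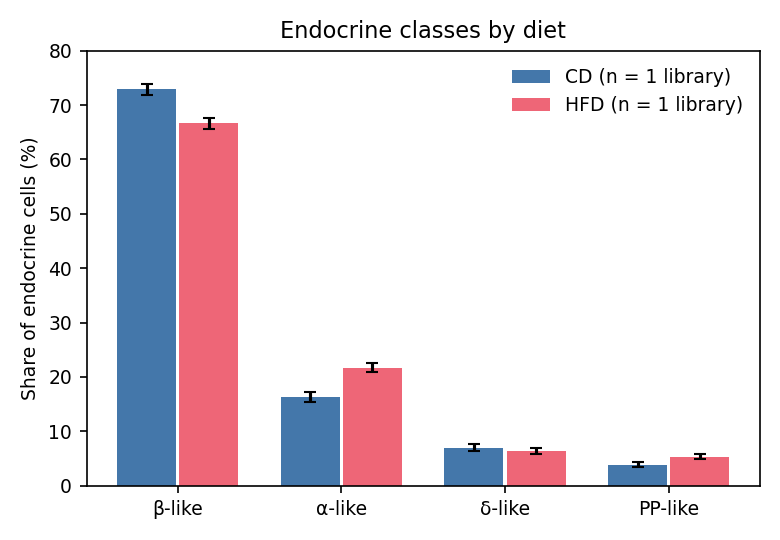
Share of endocrine cells (%) in the β-like, α-like, δ-like and PP-like classes for CD and HFD (1 library each); bars are shares and error bars exact binomial 95% intervals, which cover counting error only. The α-like bar stands at 16.3% in CD and 21.7% in HFD, and the β-like bar at 72.9% and 66.7%.

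Endothelial-like cells made up 3.73% of all kept cells in CD (3.35 to 4.15) and 4.91% in HFD (4.51 to 5.33). Macrophage-like cells made up 1.78% (1.52 to 2.08) and 2.01% (1.75 to 2.29), and mesenchymal-like cells 1.68% (1.43 to 1.97) and 1.97% (1.72 to 2.25). Ductal-like cells made up 0.224% (0.137 to 0.346) and 0.541% (0.412 to 0.698), acinar-like cells 0.224% (0.137 to 0.346) and 0.0642% (0.0258 to 0.132), and Schwann-like cells 0.179% (0.103 to 0.291) and 0.184% (0.112 to 0.283). These shares depended on how cells were classed. With a class for each cell from the marker lists acinar-like cells made up 4.94% in CD and 0.633% in HFD, ductal-like cells 1.64% and 1.73%, and Schwann-like cells 1.83% and 2.64%. No cluster took the acinar-like name at resolution 2, the macrophage-like name at resolution 0.5 or without doublet removal, or the acinar-like, macrophage-like or Schwann-like name with a UMI minimum of 3000 or a minimum per library, where the mesenchymal-like name was missing too. With each library clustered alone HFD had no acinar-like or Schwann-like cells. The naming thresholds, set after seeing the data, left 4 clusters unnamed, with 10.0% of CD cells (9.4 to 10.7) and 3.83% of HFD cells (3.47 to 4.2). One of them was led by the trypsinogen genes Try4, Prss2 and Try5 and held 543 CD and 58 HFD cells, with a median mitochondrial share of 11% over both libraries. It had 32.1% of its UMIs on Ins2 and 4.1% on Gcg, and the β-like class scored highest in it. It stayed unnamed because its top 10 genes held 0 β-like markers and 4 of other classes. The endocrine shares above leave it out, although it held 6.09% of CD and 0.532% of HFD cells. Another was led by Sst and Ly6h and held 323 CD and 309 HFD cells. It had mixed hormones, with 21% of its UMIs on Ins2, 4.21% on Ppy, 3.25% on Sst and 3.08% on Gcg at a median of 19438 UMIs. The values for δ-like cells leave it out. At resolution 0.5 the δ-like class grew to 834 CD and 907 HFD cells, 10.2% and 9.23% of endocrine cells. Of the other unnamed clusters, one carried T cell and immunoglobulin genes in 26 and 39 cells, and the last was led by haemoglobin genes in 1 and 11 cells.

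In β-like cells the metallothioneins Mt1 and Mt2, which bind zinc and copper, were lower in HFD than in CD. Mt1 (chromosome 8, 94179082 to 94180327) stood at 3901 CPM in CD and 688 CPM in HFD, a log2 ratio of -2.50 (-2.51 to -2.50), and Mt2 (chromosome 8, 94172664 to 94173568) had a log2 ratio of -2.53 (-2.56 to -2.51). Gc, the vitamin D-binding protein (chromosome 5, 89417522 to 89457898), was higher in HFD at 64.8 CPM against 12.1, a log2 ratio of 2.42 (2.35 to 2.49). Dapl1 (chromosome 2, 59484653 to 59505020) was higher at 176 CPM against 38, a log2 ratio of 2.21 (2.17 to 2.25). Cd79a, a subunit of the B cell receptor complex (chromosome 7, 24897381 to 24902197), was lower at 15 CPM against 81, a log2 ratio of -2.43 (-2.49 to -2.37). Different clusters held most β-like cells of either library, clusters 0, 4 and 10 in CD and clusters 1 and 2 in HFD, and these values compare the whole class.

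The other β-like genes that the ranking placed higher in HFD were Fam46a, a noncanonical poly(A) polymerase, with a log2 ratio of 1.90, the stress-induced regulator Nupr1 (1.29) and the nuclear noncoding RNA Neat1 (1.21). Also placed higher were the surface glycoprotein Cd200 (1.18), the RNA-binding protein Msi2 (1.15), the prolactin receptor Prlr (1.04), the actin-capping protein Tmod2 (1.03) and the endoplasmic reticulum prolyl isomerase Fkbp11 (1.03). Those placed lower were the sulfotransferase Sult1d1 (-1.53), the cold-inducible RNA-binding protein Rbm3 (-1.52) and T2 (-1.38). Further down were the thymosin Tmsb15b2 (-1.21), the nucleosome-binding Hmgn2 (-1.19) and the annexin partner S100a10 (-1.18). The insulin genes had log2 ratios of 0.14 (Ins1) and 0.091 (Ins2), and Iapp, which encodes islet amyloid polypeptide, -0.096. Ins2 alone stood at 444710 CPM in CD and 473630 CPM in HFD. These CPM are not shares of all UMIs, because the TMM factors of this class were 1.03 in CD and 0.975 in HFD. Total counts lower every β-like ratio, and the median log2 ratio of genes at 50 CPM or more was then -0.15. Without the hormone and mitochondrial genes in the scaling, 8 of the 20 ranked genes stayed in the ranking. That scaling raises every CPM, so genes under the 50 CPM limit of the main setting can enter. The median log2 ratio of genes at 50 CPM or more was -0.047 with it and -0.075 in the main setting. Over the 52 ranked gene and class pairs of all 3 classes, 0 of 1080 log2 ratios under alternatives changed sign. These pairs were selected from the same libraries for intervals far from a ratio of 1, so this was largely set by the selection and is no evidence of replication.

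Among the preset lists in β-like cells, the mitochondrially encoded genes had the highest median log2 ratio, 0.60, at percentile 100 of random lists, with mt-Co1 at 0.46 and mt-Nd3 at 1.11. The immediate early and dissociation response had a median of 0.41 (percentile 100), with the chaperone gene Hspa1b at 1.86. Cholesterol synthesis had a median of 0.30 (percentile 100), where 21 of 22 measured genes had a ratio above 1, with Hsd17b7 at 0.98. Fatty acid synthesis had a median of 0.19 (percentile 99.6), but 0.090 with the length trend removed. cAMP and incretin signalling (0.25, percentile 99.9, the phosphodiesterase Pde10a at 1.52) and amino acid transport (0.18, percentile 99.2) were also above most random lists, but the latter had a median of 0.11 with total counts and 0.10 with every cell counted alike. β identity had a median of 0.18 (percentile 99.8), with the disulfide oxidase Ero1lb at 0.90, and secretory granules 0.12 (percentile 99.3), with Vgf at 1.53 and the abundant granule protein Chga at -0.24. With total counts these medians were 0.11 and 0.046. α identity had a median of 0.28 (percentile 100) with Ttr at 0.86. δ identity had a median of 0.18 (percentile 99.2), but 6 of its 11 measured genes, among them Pax6 at 0.31, are also in β identity, so this is not a separate result, and it was 0.063 with the UMI minimum per library. Antigen presentation and interferon response had a median of 0.14 (percentile 99.7), and between 0.13 and 0.33 over the other scalings.

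The cell cycle list had a median of -0.31 in β-like cells, at percentile 0 of random lists, with the chromatin protein gene Hmgb2 at -1.08 while the abundant cyclin gene Ccnd2 stood at 0.51. Over the alternatives the median lay between -0.50 and -0.20, the latter with the length trend removed. Nuclear oxidative phosphorylation genes had a median of -0.15 (percentile 3.35), with Ndufv2 at -0.50 and Cox8a at -0.21, and glycolysis -0.17 (percentile 4.67), with Gapdh at -0.052. Both lay inside the central 95% of random lists, and the former was -0.015 with the length trend removed. The medians of the other lists were those of antioxidant and metal response (-0.097, percentile 17.3), ribosomal proteins (-0.099, percentile 40.7), the unfolded protein response (-0.043, percentile 58.1), fatty acid oxidation (-0.0043, percentile 49.2) and β immaturity and disallowed genes (0.078, percentile 92). The last of these held Aldh1a3, an aldehyde dehydrogenase, with 11 UMIs in CD and 444 in HFD, a log2 ratio of 5.47 (4.61 to 6.48). The direction of the antioxidant list depended on thinning and on transcript length, and those of the ribosomal and unfolded protein lists on transcript length. The fatty acid oxidation median had no direction, with an interval of -0.059 to 0.055 and 0.052 with the length trend removed.

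In α-like cells the gene ranked highest was Atf3. This stress-induced transcription factor gene (chromosome 1, 191170296 to 191218039) stood at 31.2 CPM in CD and 159 CPM in HFD, a log2 ratio of 2.35 (2.19 to 2.51). The noncoding RNA Bc1 (chromosome 7, 144914470 to 144914637) stood at 32.4 and 134 CPM, a log2 ratio of 2.05 (1.90 to 2.21), and the chaperone gene Dnajb1 (chromosome 8, 83608193 to 83612653) at 56.4 and 144 CPM, a log2 ratio of 1.35 (1.23 to 1.48). Lower in HFD were the tetraspanin Cd9 (chromosome 6, 125460266 to 125494791), at 103 and 29.7 CPM with a log2 ratio of -1.79 (-1.95 to -1.64), and Rbm3 (chromosome X, 8138975 to 8145880), at 206 and 74.5 CPM with a log2 ratio of -1.47 (-1.57 to -1.37).

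The ranking also placed higher in α-like cells the mRNA decay factor Zfp36 (log2 ratio 1.15), the lysosomal sulfatase Ids (1.12) and the p53 target Trp53inp1 (1.06). It also placed there the chaperone Hsph1 (0.98), the phosphatase Dusp1 (0.96), Lgals3bp (0.96) and the immediate early transcription factor Egr1 (0.87). It placed lower Basp1 (-0.97), the cold-inducible Cirbp (-0.91), the stress gene Gadd45b (-0.79), Erh (-0.78), Hmgn2 (-0.78), the selenoprotein Selenof (-0.74) and the translocon protein Ssr2 (-0.69). The glucagon gene Gcg stood at 265850 CPM in CD and 221530 CPM in HFD, a log2 ratio of -0.26. Ppy, the pancreatic polypeptide gene, was at 39296 and 51048 CPM in this class, a log2 ratio of 0.38. The value is not one of α cells alone, because without scaling within library a subcluster of 8 CD and 75 HFD cells of this class had 20.6% of its UMIs on Ppy, against 3.01% to 4.15% in the others.

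The mitochondrially encoded genes had the highest median of all lists in α-like cells, 0.75 (percentile 100), with all 13 measured genes above a ratio of 1 and mt-Co3 at 1.17. The immediate early and dissociation response had a median of 0.74 (percentile 100), with Atf3 as above and the abundant Fos at 0.059. The order of these 2 lists is not settled, since the counting interval of the latter median, 0.60 to 0.78, holds the former. Under alternatives the mitochondrial median went down to 0.53, with free RNA subtracted by the profile of barcodes with 100 to 500 UMIs. The lowest for the immediate early list was 0.57. Amino acid transport had a median of 0.49 (percentile 100), with the cationic amino acid transporter Slc7a2 at 0.76 and Slc7a8 at 0.70. α identity had a median of 0.15 (percentile 98.4), with the kinase gene Wnk3 at 0.80. β identity had a median of 0.27 (percentile 100), but 0.056 once free RNA was subtracted with the profile of barcodes with 100 to 500 UMIs. δ identity, which shares 6 of its 9 measured genes with β identity, had a median of 0.27 (percentile 98.6), but 0.058 when each cell was classed from the marker lists. The level that free RNA would bring to this class is uncertain, since its share of the sums was put at 10.1% in CD and 8.07% in HFD with the profile of barcodes with 10 to 100 UMIs and at 2.01% and 5.3% with the other. With the former Ins1 and Ins2 lay below that level, but both are among the foreign genes whose median set it, so this is no independent check. The unfolded protein response had a median of -0.20 (percentile 0.085), with the chaperones Dnajb11 at -0.79 and Hsp90b1 at -0.19. Nuclear oxidative phosphorylation genes had a median of -0.11 (percentile 1.37), with cytochrome c (Cycs) at -0.54, and glycolysis -0.18 (percentile 2.13), with Pfkl at -0.58. With the length trend removed these medians were -0.028 and -0.058, and against random lists matched on length too they stood at percentiles 14.6 and 6.15, inside the central 95%.

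The other lists in α-like cells had medians of 0.23 for fatty acid synthesis (percentile 96.1), 0.19 for antigen presentation (percentile 96.8, B2m at 0.58) and 0.17 for cholesterol synthesis (percentile 94.9, Stard4 at 0.80). They were 0.11 for fatty acid oxidation (percentile 86.4), 0.11 for cAMP and incretin signalling (percentile 87, but a median of -0.015 in thinned cells) and 0.074 for β immaturity (percentile 74.2). Cd36, a fatty acid transporter of the fatty acid oxidation list, stood at 8.15 CPM in CD and 32.4 CPM in HFD, a log2 ratio of 1.99 (1.68 to 2.31). The remaining medians were 0.034 for ribosomal proteins (percentile 79.9), 0.013 for secretory granules (percentile 63.1, Chga at -0.59), -0.11 for antioxidant and metal response (percentile 9.54, the secreted peroxidase Gpx3 at 0.67) and -0.12 for cell cycle (percentile 5.11, Ccnd2 at 0.53). All of these lay inside the central 95% of random lists, and no direction is read from them.

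In δ-like cells Bc1 was again higher in HFD, at 118 CPM against 32.5, a log2 ratio of 1.86 (1.56 to 2.17), as was Atf3 at 63.9 CPM against 19.3, a log2 ratio of 1.73 (1.33 to 2.13). Also higher were the matricellular protein gene Cyr61 (log2 ratio 1.26), Ids (1.20), Hsph1 (1.02) and Dnajb1 (0.94). Rbm3 was lower at 106 CPM against 281, a log2 ratio of -1.41 (-1.59 to -1.23). Also lower were the phosphatase inhibitor Ppp1r17 (chromosome 6, 56017497 to 56032689; -1.26), the glutathione transferase Gstp1 (-1.26), Erh (-1.18), Gadd45b (-1.18) and the kinase Pim3 (-1.16). Sst, which encodes somatostatin, stood at 97185 CPM in CD and 105900 CPM in HFD, a log2 ratio of 0.12. The sums behind these values were small, with 3762699 UMIs in CD and 3069388 in HFD. The share of free RNA in them was put at 21.5% in CD and 16.2% in HFD with the profile of barcodes with 10 to 100 UMIs, and at 4.69% and 17.0% with the other. Of the 12 ranked genes only 5 stayed in the ranking with a UMI minimum of 3000 or with each library clustered alone.

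The mitochondrially encoded genes had a median of 0.59 in δ-like cells (percentile 100), but -0.33 once free RNA was subtracted with the profile of barcodes with 100 to 500 UMIs. The immediate early and dissociation response had a median of 0.38 (percentile 100). δ identity had a median of 0.29 (percentile 100), with the receptor phosphatase Ptprz1 at 0.57, and cAMP and incretin signalling 0.25 (percentile 99.5), the latter with a median of 0.12 under the least favourable alternative. Of the 12 measured δ identity genes, 6 are also in β identity and 3 in α identity, so the δ identity median is not separate from theirs. The unfolded protein response had a median of -0.31 (percentile 0.045), with Pdia6 at -0.68 and Hsp90b1 at -0.40, and nuclear oxidative phosphorylation genes -0.25 (percentile 0.26), with Ndufa4 at -0.52. The medians nearest 0 over the alternatives were -0.15 and -0.095. α identity (0.34, percentile 99.9) and β identity (0.16, percentile 99) were higher, but the α identity median was negative under 6 of the settings, among them clustering without hormone genes (-0.40), and the β identity median was -0.046 with 2 times as many doublets removed and -0.25 once free RNA was subtracted with the profile of barcodes with 100 to 500 UMIs.

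The other δ-like medians were 0.23 for fatty acid synthesis (percentile 96, Acly at 0.58), 0.18 for amino acid transport (percentile 92.6, Slc38a2 at 0.53), 0.17 for β immaturity (percentile 94.5), -0.0046 for antigen presentation (percentile 53.8, H2-D1 at -0.53) and -0.11 for cholesterol synthesis (percentile 11.8). Further medians were -0.15 for ribosomal proteins (percentile 54.9, but 0.035 with the length trend removed), -0.16 for antioxidant and metal response (percentile 25.7) and -0.17 for secretory granules (percentile 20.7, Pcsk2 at 0.41). The last were -0.19 for fatty acid oxidation (percentile 4.76), -0.22 for glycolysis (percentile 6.75, Gpi1 at -0.59) and -0.24 for cell cycle (percentile 4.51, Tubb5 at -0.56, but a median of 0.026 with 2 times as many doublets removed). All of these lay inside the central 95% of random lists, and no direction is read from them.

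**Figure D2:**
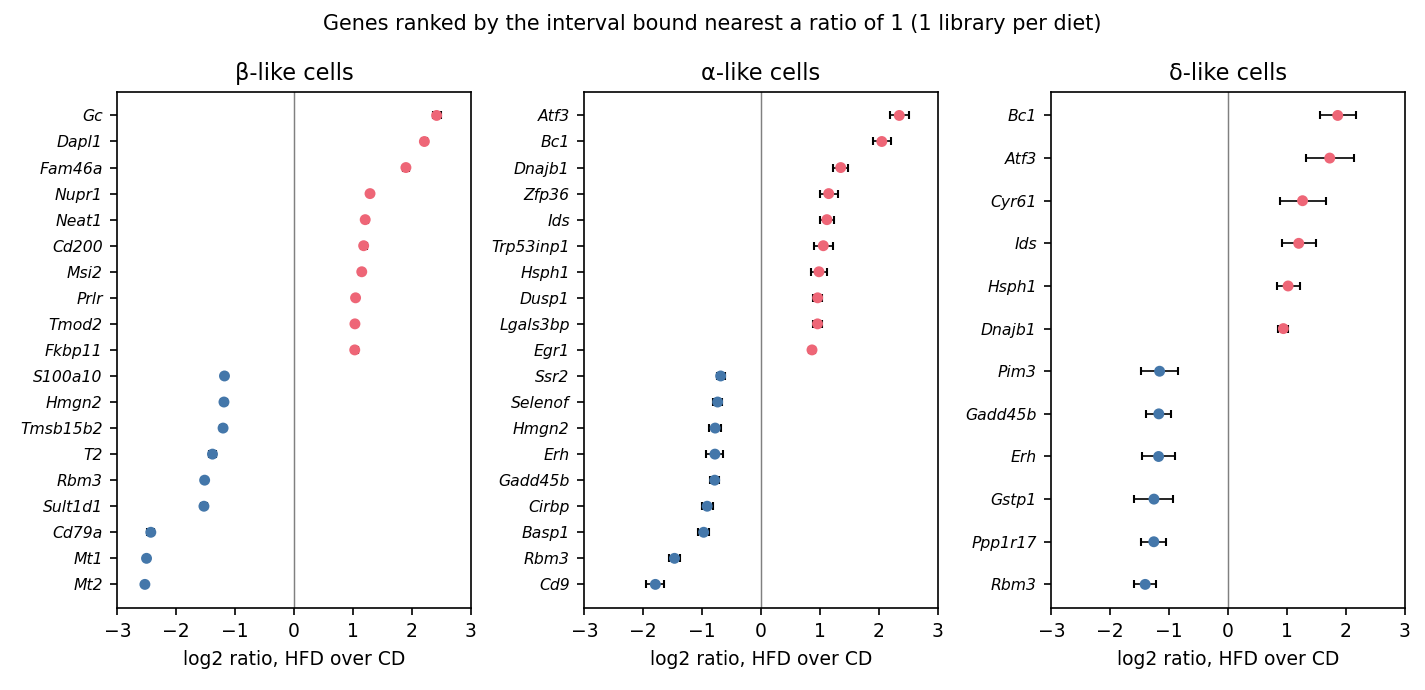
Log2 ratio of HFD to CD (horizontal axis) for ranked genes of the β-like, α-like and δ-like classes, from 1 library per diet; points are ratios of scaled UMI sums, red above and blue below a ratio of 1, and error bars are exact 95% intervals that cover counting error only. Rbm3 stands at -1.52, -1.47 and -1.41 in the 3 classes, and Mt2 and Mt1 have the lowest ratios in β-like cells.

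**Figure D3:**
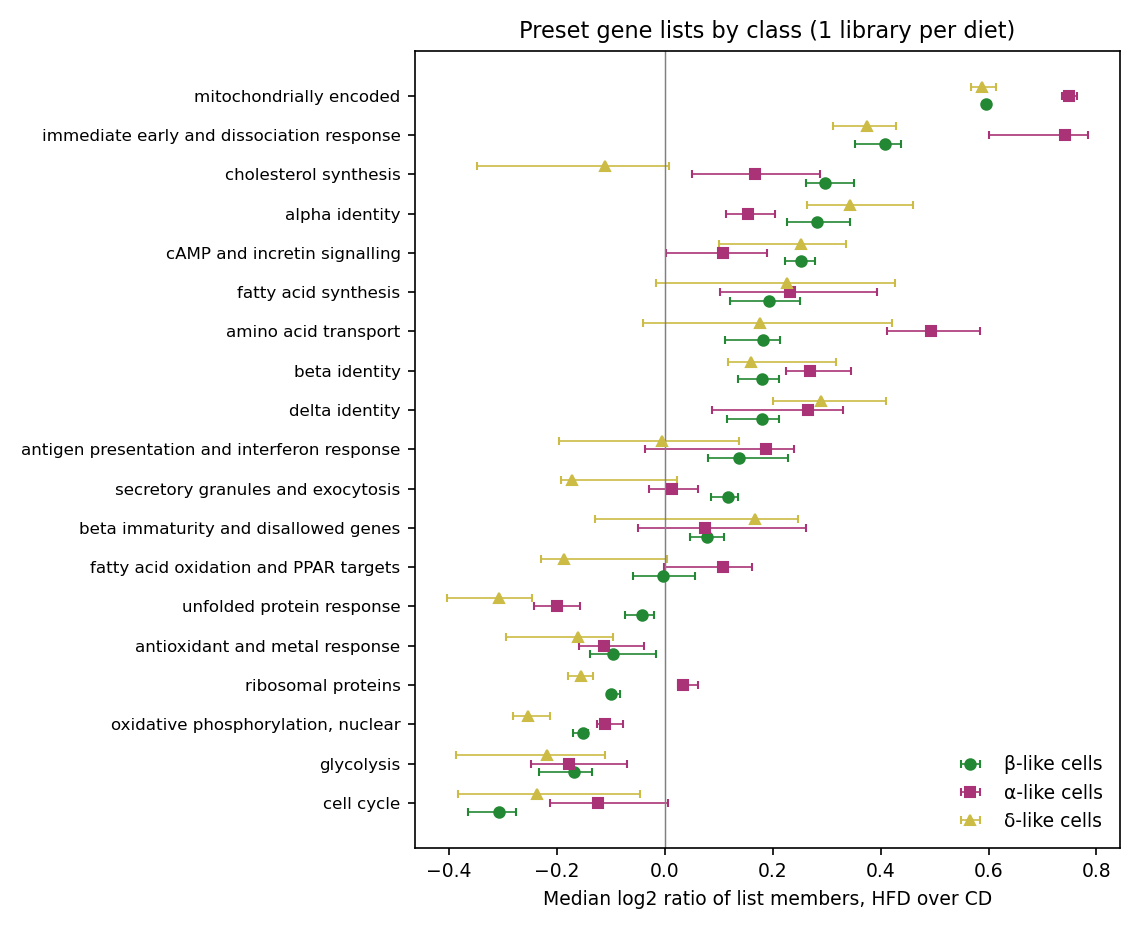
Median log2 ratio of HFD to CD (horizontal axis) over the members of each preset gene list in β-like (circles), α-like (squares) and δ-like cells (triangles), from 1 library per diet; error bars are 95% intervals of the median from Poisson redraws and cover counting error only. The mitochondrially encoded list stands highest in each class, at 0.60, 0.75 and 0.59 as scaled in the main setting.

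Subpopulations were sought within each class after scaling within library. β-like cells fell into 7 subclusters, α-like cells into 4 and δ-like cells into 3. Among β-like subclusters one of 480 cells was marked by the proliferation genes Stmn1, Cenpf, Ube2c and Top2a and one of 80 cells by the interferon-induced genes Ifit1, Rsad2 and Bst2. Others were marked, one of 3273 cells by Pappa2, Pdyn, Cox6a2 and Dapl1, and one of 2469 cells by Cd79a, Pyy and Ppy. Over the whole β-like class Ppy lay near the level of free RNA. It stood at 779 CPM in CD and 1027.5 in HFD, where free RNA would bring 764 and 1021.5. Ppy is itself one of the foreign genes whose median set that level, and only 4 genes entered the median in HFD. The closeness is therefore partly built in and does not show where the Ppy UMIs came from. A pair of low-depth β-like subclusters was led by mt-Nd6 and Malat1 (618 cells, median mitochondrial share 9.61%) and by Gcg, Apoe and Ppy (110 cells, 11.8%), and the largest, of 4595 cells, by AY036118, S100a6 and Spp1. The α-like subclusters were led by Id1, Id3 and Sox4 (1597 cells), by Ppy, 8430408G22Rik and Tspan8 (813 cells), by haemoglobin genes (639 cells) and by Slc2a2 and mt-Nd6 (190 cells). The last was also of low depth, with a median of 3620 UMIs and a median mitochondrial share of 8.81%. Its 10 leading genes included Ins1, Ins2, Iapp and Sst, hormone genes of other classes. The δ-like subclusters were led by Cd79a, Gcg and G6pc2 (260 cells), by Hspb1, Arc and Dnajb1 (402 cells) and by Dlk1 and Sycn (449 cells). The last also had Try4, Zg16 and Cela1 among its 10 leading genes, and Sycn, Try4 and Zg16 were leading genes of the acinar-like cluster too. The group led by Cd79a also had Slc30a8 of the β identity list and Slc7a2 of the α identity list among its leading genes. It had 4.06% of its UMIs on Ins2, against 2.55% and 2.68% in the others, and 7.59% on Sst, against 10.7% and 11.2%. In the group led by Hspb1, leading genes included Dnajb1, Dusp1, Hspa1a, Nr4a1, Ier2 and Fos of the immediate early and dissociation list. Every subcluster had at least 1 leading gene that differed over 1.5 times between the class sums of the libraries, so sizes were not compared between diets. The number of subclusters ranged from 4 to 13 for β-like, 1 to 7 for α-like and 1 to 8 for δ-like cells over resolutions 0.2 to 0.8. As whole groupings they overlapped little, with adjusted Rand indices against the subclusters described here of 0 to 0.304 over these resolutions. Without scaling within library they were 0.158 for β-like, 0.199 for α-like and 0.0737 for δ-like cells, and the most uneven subcluster took 98.2%, 95.9% and 91.4% of its cells from 1 library. The index of 0 is fixed where α-like or δ-like cells form 1 subcluster. Some β-like groups recurred by their leading genes. The proliferation group held 465 cells at resolution 0.2, 479 at 0.8 and 463 without scaling within library, and the group led by Gcg and Apoe 110 in each. The interferon group did not recur at resolution 0.2, and the larger groups split or merged.

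Cell cycle transcripts were found in fewer β-like cells of HFD than of CD at matched depth. At least 2 of the genes Mki67, Top2a, Cdk1, Ccna2, Birc5 and Ube2c, which mark dividing cells, were detected in 162 of 5208 CD cells (3.11%, 2.66 to 3.62) and 116 of 6229 HFD cells (1.86%, 1.54 to 2.23), a difference of -1.25 percentage points (-1.85 to -0.664). Thinning left out 134 CD and 54 HFD cells, and without thinning the shares were 4.83% and 3.29%. No α-like cell passed in either library, 0 of 1157 in CD and 0 of 1953 in HFD, which allows shares of up to 0.259% and 0.154% at median depths of 9412 and 7667 UMIs before thinning; thinning left out 39 and 90 cells, and the unthinned shares were 0.167% and 0.0489%. No δ-like cell passed either, 0 of 502 and 0 of 547, which allows up to 0.598% and 0.548%, with 9 and 53 cells left out and unthinned counts of 1 of 511 and 0 of 600. The β-like subset is defined by genes of the cell cycle list, so its share and that list's median are not independent of each other.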

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

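The tests of digestion and of doublets among cycling cells were written before the values they measure were seen, and the tests of free RNA, damaged cells, transcript length, the mitochondrial limit, doublet removal and the UMI minimum for the α-like share were chosen only after the result was seen.

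Barcodes with 10 to 100 UMIs, which are not cells and gave the free RNA profile, had 19.3% of their UMIs on mitochondrially encoded genes in HFD and 8.8% in CD. Of the barcodes with at least 1500 UMIs, 16.6% failed the mitochondrial limit in HFD and 6.68% in CD. The surface glycoprotein gene Cd200 had a log2 ratio of HFD to CD of 1.18 in β-like cells, -0.15 in α-like cells and -0.52 in δ-like cells, differences of 1.33 and 1.70. The thymosin gene Tmsb15b2 had log2 ratios of -1.21 in β-like and 0.26 in α-like cells, a difference of -1.46. These differences between classes were not tested, since either diet has 1 library.

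The median ratio of mitochondrially encoded genes was above 1 in HFD against CD in β-like, α-like and δ-like cells, though mt-Nd6 had a log2 ratio of -0.044 in β-like cells, and that of nuclear genes of oxidative phosphorylation was below 1. In β-like cells the nuclear list stood at percentile 3.35 of random lists, inside the central 95%, with 14 of 47 genes above a ratio of 1. Free RNA is argued against as the whole cause in β-like and α-like cells, where the lowest list median after subtraction was 0.42 over both profiles, but in δ-like cells the median was 0.52 with one profile and -0.33 with the other, which leaves it open. Loss of cytoplasmic RNA from damaged cells stays open, since the median of 5 nuclear RNAs was 0.45 in β-like, 0.21 in α-like and 0.53 in δ-like cells. The lower nuclear medians may follow a trend of the ratio with transcript length (Spearman's rho across genes, which are not independent replicates, 0.405, 0.425 and 0.438), because without the trend their median was -0.015 in β-like, -0.028 in α-like and -0.095 in δ-like cells, the last too far from 0 to settle it. Against random lists matched on length too, the nuclear list stood at percentiles 30.9, 14.6 and 2.31, the δ-like value still outside the central 95%. The trend was fitted with genes of this list included, so its removal can take out part of their own difference. An effect of diet on mitochondrial transcripts also stays open and was not tested.

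The α-like share of endocrine cells was higher in HFD. Doublet removal is argued against as its whole cause, since the difference was 5.2 percentage points without it. The difference was 5.16 with a mitochondrial limit of 25% and 5.01 with a minimum of 800 UMIs. Those settings added too few cells to decide, so both limits stay open. With 25%, kept cells rose from 8919 to 9104 in CD and from 10898 to 11396 in HFD. The main mitochondrial limit had failed 709 and 2420 barcodes. With 800 UMIs, kept cells rose to 9037 and 11026. The rule that assigns cells moved the difference more than these settings did, with 2.7 points when each cell was classed from the marker lists. Digestion or dispersal that differed between the libraries cannot be told apart from diet, because there is 1 library per diet. A change in islet composition with diet stays open and was not tested.

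Fewer β-like cells of HFD had cell cycle transcripts. Doublet removal is argued against, since with doublets put back, among barcodes with at least 30% insulin UMIs, the difference was -0.808 percentage points (-1.3 to -0.328), against -0.816 (-1.35 to -0.29) with doublets removed by the same insulin limit. Free RNA carrying these transcripts is argued against by α-like cells of CD, where 0 cells passed and the counts allow at most 0.259%. An effect of diet on division stays open and was not tested, as does variation between animals.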

How the results depend on the processing

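The removal of the trend with transcript length was chosen after seeing the data, as were the rule that a single gene counts as turned only if its interval excludes a ratio of 1 and its level is at least 3 times that of free RNA, and the limit of 2 members per list; the other alternatives were fixed before the data were examined. No paired analysis was possible because each diet has 1 library, and no replicate could be left out. The δ-like class was absent under the UMI minimum per library, acinar-like, macrophage-like, Schwann-like or mesenchymal-like cells were absent under it or others, and the ranking was not made anew with every cell counted alike or with the length trend removed. Of 57 list and class pairs, 29 had a median outside the central 95% of random lists, and the medians of 3 of these changed sign under some alternative, all in δ-like cells. All 12 pairs of a hormone gene or Ttr and a class where it lay near the level of free RNA changed sign under at least 1 alternative. Depth limits δ-like cells, where the interval lay on the right side of 1 for 88% of simulated 1.5-fold changes of genes at 20 CPM or more. Where a value is given below, the cause was not tested. Values given below for single genes have the sign opposite to the main setting, where in δ-like cells Npy was at 2.34 (10 and 41 UMIs), Insig1 at -0.80, Gcgr at -1.45 (27 and 8 UMIs), Ppy at 0.090, Pyy at -0.079 and Rpl41 at -0.14. In β-like cells Hadh was at 0.063, Rpl41 at 0.025, Gapdh at -0.052 and Iapp at -0.096, and in α-like cells Pyy was at -0.055, Rbp4 at 0.067 and Rpl13 at -0.018.

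With a UMI minimum of 3000 the share differences were -3.42 percentage points for β-like, -2.93 for δ-like and 0.656 for PP-like cells, 5 of 12 δ-like genes stayed in the ranking, the α identity median in δ-like cells was -0.51, Ppy in δ-like cells -0.24 and Pyy in α-like cells 0.034. With a minimum of 800 the β-like and δ-like differences were -3.97 and -2.37 points, 6 δ-like genes stayed, α identity in δ-like cells was -0.52 and Ppy there -0.22. With the minimum per library 17 of 21 lists stayed outside the central range. With a mitochondrial limit of 10% the β-like and δ-like differences were -3.36 and -2.34 points, 6 δ-like genes stayed, α identity in δ-like cells was -0.43 and Ppy there -0.12, and with 25% 7 δ-like genes stayed. With 2 times as many doublets removed, β identity in δ-like cells was -0.046, cell cycle there 0.026, Npy there -0.74 and Pyy in α-like cells 0.039.

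Clustering without hormone genes gave -4.01 points for β-like and -2.34 for δ-like cells, kept 6 δ-like genes, and gave -0.40 for α identity and -0.49 for Ppy in δ-like cells. Each library clustered alone gave 7.48 points for α-like and 0.641 for PP-like cells, kept 5 δ-like genes, and gave -0.31 for α identity and -0.24 for Ppy in δ-like cells. A class for each cell from the marker lists gave -0.747 points for β-like, 2.7 for α-like and -0.925 for PP-like cells, kept 7 δ-like genes, and gave 0.022 for Insig1 and -0.025 for Ppy in δ-like cells and 0.063 for Pyy, -0.00602 for Rbp4 and 0.0104 for Rpl13 in α-like cells. At resolution 0.5, 7 δ-like genes stayed, α identity in δ-like cells was -0.23, Ppy there -0.26, Gcgr 0.089 and Insig1 0.37, and at resolution 2 Pyy in α-like cells was 0.022. Subclusters numbered 4, 1 and 1 in β-like, α-like and δ-like cells at resolution 0.2, and 13, 7 and 8 at 0.8.

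Total counts gave -0.0098 for Hadh and -0.048 for Rpl41 in β-like cells, and scaling without hormone and mitochondrial genes kept 8 of 20 β-like genes. Thinning gave 0.0086 for Gapdh and 0.014 for antioxidant and metal response in β-like cells and -0.0147 for cAMP and incretin signalling in α-like cells. Free RNA subtracted with the profile of barcodes with 100 to 500 UMIs gave -0.25 for β identity and -0.33 for mitochondrially encoded genes in δ-like cells. With the length trend removed Iapp was 0.078 in β-like, Pyy 0.10 and Rpl41 0.049 in δ-like and Rpl13 0.10 in α-like cells, and in β-like cells antioxidant and metal response was 0.059, ribosomal proteins 0.082 and the unfolded protein response 0.078, with ribosomal proteins 0.035 in δ-like cells. With at least 1 cell cycle gene detected the differences were -0.461 points in α-like and -1.09 in δ-like cells.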

Other observations

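The genes and shares in this part were chosen after their values were seen, no test was run on them, and no explanation is offered.

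Dbp, a transcription factor that follows the clock, had a log2 ratio of HFD to CD of -1.18 in β-like cells (-1.24 to -1.12), -0.93 in δ-like cells (-1.15 to -0.71) and 0.19 in α-like cells (-0.17 to 0.55). The repressor Nr1d1 stood at -0.77 in β-like cells, -0.81 in δ-like cells and 1.13 in α-like cells (0.56 to 1.72, from 35 and 101 UMIs), and Nr1d2 at 1.20 in α-like cells, 0.02 (-0.03 to 0.07) in β-like cells and -0.19 (-0.44 to 0.07) in δ-like cells. Other clock genes looked at went both ways in β-like cells. Hlf (-1.12), Per3 (-0.43), Ciart (-0.29) and Tef (-0.28) were lower in HFD, while Arntl (0.56) and Per1 (0.32) were higher. Per2 (-0.08 to 0.17) and Npas2 (-0.85 to 1.30) had no clear direction there. The cold-inducible RNA-binding genes Rbm3 and Cirbp were lower in HFD in each of the 3 classes, with log2 ratios of -1.52, -1.47 and -1.41 for Rbm3 and -0.90, -0.91 and -0.64 for Cirbp in β-like, α-like and δ-like cells.

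The β cell maturity genes Ucn3 and Mafa, which encode urocortin 3 and an insulin gene activator, were higher in HFD in β-like cells, with log2 ratios of 0.90 and 0.70. Aldh1a3, an aldehyde dehydrogenase gene, was detected in 0.206% of unthinned β-like cells in CD (0.103 to 0.368) and 4.81% in HFD (4.29 to 5.36), and in 0.0192% and 0.706% after thinning, with 134 and 54 cells left out. In α-like cells, with median depths of 9412 and 7667 UMIs against 26734 and 23499 in β-like cells, the unthinned shares were 0.0836% and 0.294%. In δ-like cells, with median depths of 6429 and 4854 UMIs, they were 2.35% in CD (1.22 to 4.07) and 1.83% in HFD (0.919 to 3.26), and after thinning 0.797% (0.218 to 2.03) and 1.1% (0.404 to 2.37).

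Cd79a, a B cell receptor gene, was detected in 51.7% of unthinned β-like cells in CD (50.3 to 53.0) and 17.7% in HFD (16.8 to 18.7), and in 18.4% and 4.22% after thinning. Detection of Cd79a in other classes is not set against this, because in α-like cells it stood at 4.4 and 1.54 CPM where free RNA would bring 5.94 and 1.46, and in δ-like cells at 23.3 and 7.53 CPM where it would bring 12.6 and 2.94. Its partner Cd79b had 0 UMIs in the β-like, α-like and δ-like sums of both libraries. At least 2 of 5 interferon-induced genes were detected in 0 of 5208 thinned β-like cells in CD, which allows up to 0.0576%, and in 21 of 6229 in HFD (0.337%, 0.209 to 0.515), while without thinning the shares were 1.16% and 1.96%, and in thinned α-like cells 0 of 1157 and 0 of 1953. In δ-like cells 6 of 502 thinned cells passed in CD (1.2%, 0.44 to 2.58) and 6 of 547 in HFD (1.1%, 0.404 to 2.37), and the unthinned shares were 2.94% and 2.17%.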
